A study of Mus musculus with 13 samples.

How the data were processed

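RNA was measured in 13 libraries of CD4+YFP+ splenic cells from mice around 4 to 5 weeks old. The YFP reporter marks cells that express Foxp3, the transcription factor that defines regulatory T (Treg) cells. Of these, 7 libraries came from Foxp3-YFPCre mice (control) and 6 from mice heterozygous for that Cre allele, per the labels, in which it deletes Stk3 and Stk4, the kinases MST2 and MST1 of the Hippo pathway (deleted). Complementary DNA was made with the SMART-Seq v4 Ultra Low Input kit, per the labels' protocols. Libraries are named by group and replicate number. The labels do not say which mouse each library came from, so p-values measure the spread between libraries.

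The authors deposited raw read counts per gene. FeatureCounts 2.0.1, edgeR 3.28, DESeq2 1.26.0 and the builds GRCm38 and mm10 are named, per the submitters' processing notes. The aligner, the annotation and the strand setting are not given in the sources used here. The authors' deposited table of differential expression gives log2 fold changes of deleted over control, p-values and false discovery rates from several tools, together with their mean and maximum, per the file headers. Columns of group mean counts, a signal per group in the deposited tables, were not used. The count table held 26720 genes with NCBI gene numbers, of which 25623 had a symbol in the table and 93.6% matched the reference gene table of the same build, from which coordinates were taken. Each listed gene had a read in at least 2 libraries. Total counts ranged from 2671660 to 8323919 per library. Genes encoded by mitochondrial DNA were not analysed here, so that the list of them has no result.

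Genes were kept by edgeR's filterByExpr, scaled by the trimmed mean of M values (TMM) and tested with edgeR 4.0.16 (R 4.3.3), by the quasi-likelihood F test with genotype as the only term. P-values were adjusted by Benjamini-Hochberg, with 0.05 as threshold. Levels are TMM-scaled counts per 1e6 counts (CPM). On simulated counts of 23595 genes for this comparison, the test recovered 40 of 100 genes changed by a factor of 2 and 96 of 100 changed by a factor of 4, with 3 false calls. With 6 against 7 libraries at this depth, changes of a factor of 2 were therefore often missed.

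Before the data were examined, 22 testable gene lists of Treg biology, Hippo signalling, metabolism and RNA quality were fixed, with 12 lists of other cell types and sex-linked genes. Lists were tested two-sided with camera in limma 3.58.1, on voom values with a preset correlation of 0.01, and again with a correlation estimated per list. Genes named were Stk3, Stk4, Foxp3 and Rela, the 8 largest changes in each direction past the threshold with an average log2 CPM of at least 3 (without predicted genes, pseudogenes, antigen receptor segments and sex-linked genes), and up to 3 members of each list with the smallest p. A list with no member past the threshold gave its member of smallest p. Genes outside this rule are named as chosen after their values were seen.

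Alternatives fixed before the data were examined were DESeq2 size factors, upper quartile scaling, DESeq2 1.42.0, limma-voom with sample weights, no low-count filter, a filter of 10 CPM in 6 libraries, the replicate number as a block, 1 surrogate variable from sva 3.50.0, fry, each library left out in turn, and a log2 fold change of at least 1. A sex covariate was not run. Of the sex-linked list, 0 of 6 Y-linked genes were in the count table. Xist and Tsix were in it but were not used to assign sex.

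Further alternatives were chosen after seeing the data, because olfactory and vomeronasal receptor genes, which T cells do not use, had counts in every library. They were a fit restricted to genes of at least 50 mean CPM (called expressed genes here), scaling by those genes, the log share of receptor counts as a covariate, and a fit on the 5 deleted and 4 control libraries with a receptor share of 0.7 to 1.4%. The cutoff of 50 was picked after fits at 30, 64, 100 and 200 mean CPM had been seen, and the library range after the shares and a trial fit had been seen. All of these cutoffs are reported. The libraries with a receptor share of 0.7 to 1.4% are called libraries of similar receptor share. Among them, deleted replicates 2, 3, 4 and 5 (1.14 to 1.36%) still lay above every control library (0.761 to 1.07%). Counts per kb were taken over receptor genes and V segments with an annotated span of at most 1200 bp. Group differences in library measures were tested by two-sided exact permutation tests.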

Results

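The data are read counts per gene from 13 libraries of splenic Treg cells sorted on CD4 and a Foxp3 reporter, 7 from control mice and 6 from mice in which a Foxp3-driven Cre deletes Stk3 and Stk4. The labels mark the Cre allele as heterozygous in the deleted group and give no zygosity for the control group, so Cre dose was not separated from the deletion. Foxp3 lies on chromosome X, so in heterozygous females part of the Treg cells would carry the active Cre allele, and the YFP sort takes those cells. The sex of the mice is not stated in the labels, but heterozygosity at a gene on chromosome X implies females in the deleted group. The sex of the control mice stays unknown. Total counts averaged 3616413 ± 621524 (SD, n = 6) in the deleted group and 5667337 ± 1682245 (SD, n = 7) in the control group, a difference beyond the spread (two-sided exact permutation p = 0.00816). Olfactory and vomeronasal receptor genes, which serve sensory neurons, had counts in every library. Their share of the total count was 1.29 ± 0.367% (SD, n = 6) in deleted and 0.712 ± 0.256% (SD, n = 7) in control libraries (two-sided exact permutation p = 0.00641). The median log2 fold change of these receptor genes between the groups was 0.58, whereas that of genes with at least 50 mean CPM was -0.35.

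**Figure D1:**
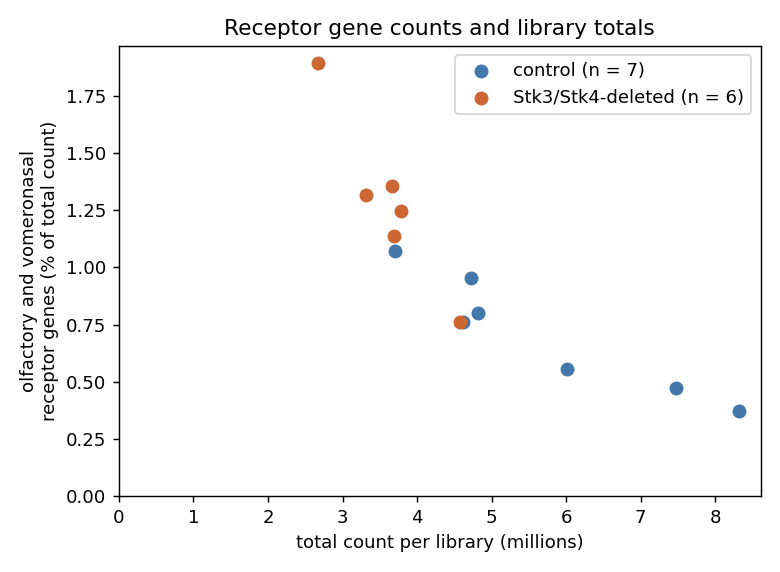
Share of the total count on olfactory and vomeronasal receptor genes (percent, vertical axis) against total count (in units of 1e6, horizontal axis), 1 point per library, with control libraries (n = 7) in blue and Stk3/Stk4-deleted libraries (n = 6) in orange. Deleted libraries lie between 0.761 and 1.89% and control libraries between 0.371 and 1.07%.

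The comparison of deleted with control Treg cells addresses what Stk3 and Stk4 contribute to the Treg transcriptome. Of 30 genes of activated, effector Treg cells, 21 fell in the deleted libraries and 9 did not pass the test. The list was lower by camera with a preset correlation, over all genes and among expressed genes. With the preset correlation the camera call also stayed with the receptor share as a covariate (adjusted p = 6.31e-16). An estimated correlation ended the call over all genes (adjusted p = 0.1), among expressed genes (adjusted p = 0.111) and with that covariate (adjusted p = 0.0574). The call stayed in libraries of similar receptor share (adjusted p = 0.023). There, deleted replicates 2, 3, 4 and 5 still had larger shares than every control library, so receptor share was not separated from genotype. The chemokine receptor gene Cxcr3 (gene number 12766; GRCm38 chromosome X, 101731535 to 101734147) was at 5.75 ± 3.94 CPM (SD, n = 6) against 86.1 ± 32.7 CPM (SD, n = 7), a log2 fold change of -3.90 (SE 0.37, adjusted p = 4.2e-06). Klrg1, an inhibitory receptor of terminally differentiated Treg cells, changed by -3.16 (SE 0.41), Penk, which encodes proenkephalin, by -3.75 (SE 0.43), and Cd83, an activation marker, by -3.27 (SE 0.34). Each of these genes was below the lowest control library in 6 of 6 deleted libraries. In the deleted libraries Cxcr3 was near background level. The median olfactory receptor gene there averaged 17.5 counts, at a mean total of 3616413. The size of the Cxcr3 fold change is therefore uncertain. With the receptor share as a covariate Klrg1 was at -1.88 (SE 0.48, adjusted p = 0.11) and did not pass the test, while Cxcr3, Penk and Cd83 did. Foxp3 was at 44.0 ± 16.2 CPM in deleted and 54.1 ± 12.1 CPM in control libraries, with a log2 fold change of -0.30 (SE 0.24, adjusted p = 0.463) that did not pass the test.

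The targeted genes were read first. Stk3 (gene number 56274; chromosome 15, 34875499 to 35155882) was at 33.6 ± 6.32 CPM in deleted and 33.9 ± 7.51 CPM in control libraries, with a log2 fold change of -0.01 (SE 0.20, adjusted p = 0.981). Stk4 (gene number 58231; chromosome 2, 164074113 to 164155524) was at 171 ± 120 CPM against 213 ± 55.9 CPM, with a log2 fold change of -0.31 (SE 0.33, adjusted p = 0.576). Deleted replicate 1, at 394 CPM, lay above the highest control library (291 CPM), and 3 deleted libraries lay below the lowest. Without deleted replicate 1 the log2 fold change of Stk4 was -0.75 (adjusted p = 0.0789), which did not pass the test. Counts over a whole gene do not show the loss of single exons, so these values check nothing about the labels. Rela (gene number 19697; chromosome 19, 5637442 to 5648134), which encodes the NF-kB subunit p65, fell by 0.89 (SE 0.26, adjusted p = 0.0311). Among expressed genes alone Rela did not pass the test, with -0.50 (SE 0.21, adjusted p = 0.0772).

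Of 24068 genes tested, 400 were higher and 2050 lower in the deleted libraries. The split depended on the scaling: upper quartile scaling gave 761 higher and 1208 lower, and scaling by expressed genes, which moved genes by a median of 0.36, gave 1213 higher and 684 lower. Among the 5153 expressed genes tested alone, 561 were higher and 717 lower, of which 35 and 717 were also called over all genes. With the receptor share as a covariate, which had a correlation of 0.725 with genotype, 36 genes were higher and 36 lower. Of the 53 genes called lower that the naming rule picked, 12 also passed with this covariate: Cxcr3, Penk, Cd83, Nkg7, S100a6, Nt5e, Tigit, Ccr6, Hspa1a, Hspa1b, Bcl2a1b and Bcl2a1d. The other 41 did not, among them Klrg1, Il2rb (adjusted p = 0.442), Ccl5 (adjusted p = 0.471), Pdcd1 (adjusted p = 0.13), Icos (adjusted p = 0.139) and Aldoa (adjusted p = 0.314). The median of the 53 was -1.62 without and -0.80 with the covariate, and their median SE was 0.28 and 0.30. The median log2 fold change went from 0.37 for genes with an average log2 CPM under 2 to -0.94 for those of 8 or more.

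**Figure D2:**
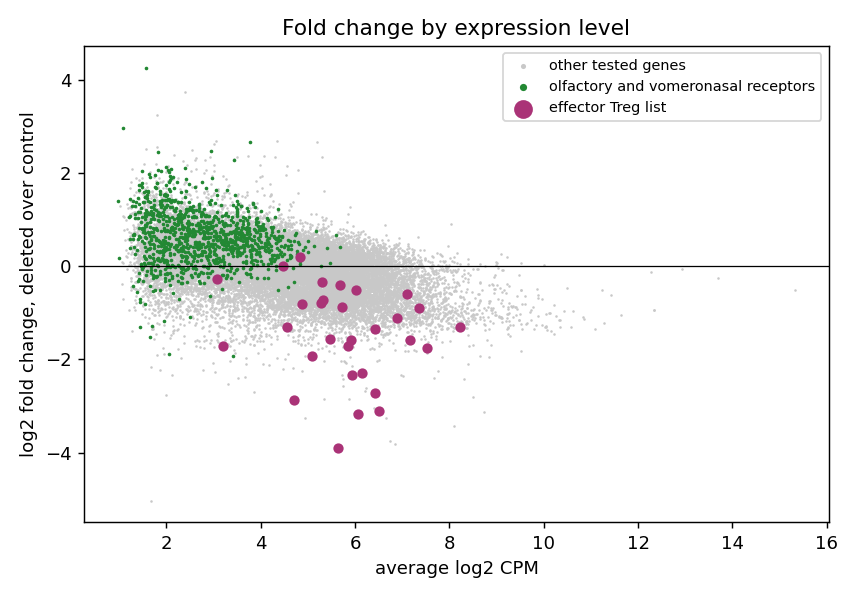
Log2 fold change of deleted over control (vertical axis) against average log2 CPM (horizontal axis) for the 24068 tested genes, 1 point per gene, with olfactory and vomeronasal receptors in green and the effector Treg list in purple. Receptor genes have a median of 0.58 and the effector list a median of -1.32.

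Of the 30 measured effector Treg genes, 21 fell, 0 rose and 9 did not pass the test (25 fell when adjusted over the list alone). Besides Cxcr3 and Klrg1, the ecto-5'-nucleotidase gene Nt5e fell by 2.71 (SE 0.29), the inhibitory receptor gene Tigit by 2.87 (SE 0.32) and the calcium-binding protein gene S100a6 by 3.10 (SE 0.45). The list's median was -1.32, lower than other genes by camera (adjusted p = 1.93e-21; adjusted p = 0.1 with an estimated correlation). Among expressed genes alone, 12 of its 17 measured members fell, with a median of -1.13 (adjusted p = 8.35e-10; adjusted p = 0.111 with an estimated correlation). The deleted libraries had the larger receptor share, as given above.

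**Figure D3:**
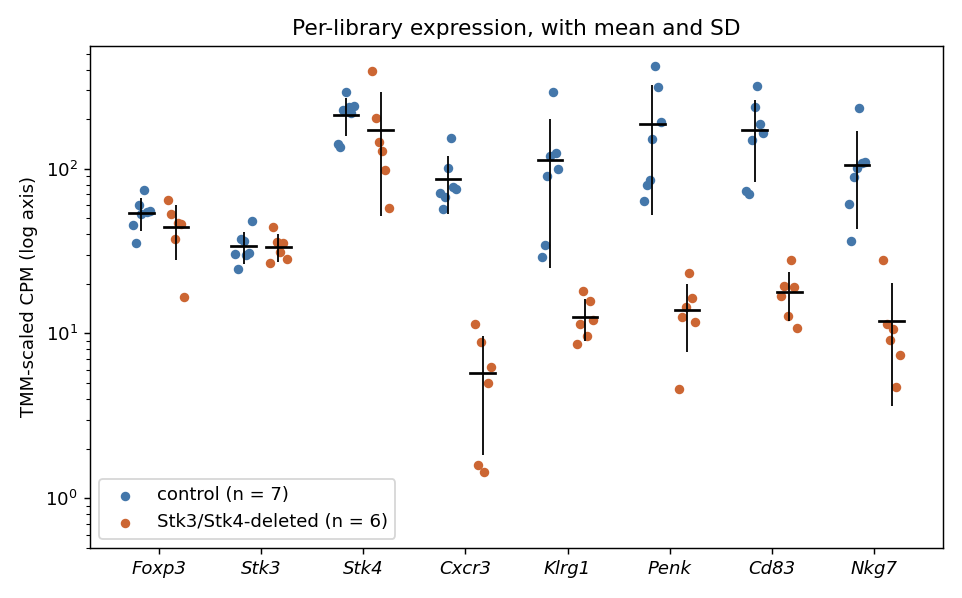
TMM-scaled CPM per library (log axis) of Foxp3, Stk3, Stk4 and 5 genes lower in the deleted libraries, 1 point per library, with control (n = 7) in blue and Stk3/Stk4-deleted (n = 6) in orange; horizontal lines are means and vertical lines SDs. Cxcr3 averages 5.75 CPM in deleted and 86.1 CPM in control libraries, while Stk3 averages 33.6 and 33.9 CPM.

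In the Treg signature list, 14 of 21 genes fell and 0 rose (18 fell when adjusted over the list alone). Its members included Penk, Cd83 and the interleukin-2 receptor beta chain gene Il2rb, which fell by 1.70 (SE 0.30). Camera gave an adjusted p of 4.12e-15 (adjusted p = 0.129 with an estimated correlation). Among NF-kB target genes, 16 of 30 fell and 0 rose (19 fell and 1 rose when adjusted over the list alone), with Cd83, Bcl2a1b (-2.84, SE 0.30) and Bcl2a1d (-2.24, SE 0.28) at the smallest p. Bcl2a1b and Bcl2a1d are near-identical copies, so their separate values are uncertain. Camera gave an adjusted p of 2.84e-12 for the NF-kB list (adjusted p = 0.129 with an estimated correlation). Among expressed genes alone, 9 of 16 Treg signature genes fell, with a median of -0.85 (adjusted p = 4.78e-09; adjusted p = 0.137 with an estimated correlation). There 7 of 16 NF-kB target genes fell, with a median of -0.31 against -0.75 over all genes (adjusted p = 0.000279; adjusted p = 0.167 with an estimated correlation). The deleted libraries also had the larger receptor share. With that share as a covariate, camera with the preset correlation still called both lists lower (adjusted p = 5.11e-06 and 0.00294). With an estimated correlation neither was called there. Some B cell and antigen presentation genes, chosen after their values were seen, were lower in the deleted libraries as well: Ighm fell by 2.81, Cd74 fell by 1.85 and Cd79b fell by 1.52, while the B cell gene Ms4a1 rose by 0.64.

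Of 21 resting Treg genes, Il7r (-1.13, SE 0.28) and Id3 (adjusted p = 0.0237) fell and 19 did not pass the test (2 fell when adjusted over the list alone; camera adjusted p = 0.23). Among expressed genes alone, a fit whose scaling moved its genes up by a median of 0.41, 4 of 19 rose (Klf3, Klf2, Satb1 and Lef1, named after their values were seen) and Il7r and Id3 fell. The list's median was then 0.19 and it was not called (adjusted p = 0.164; adjusted p = 0.597 with an estimated correlation). Over all genes camera called the list lower without deleted replicate 1 (adjusted p = 0.0382) and without control replicate 2 (adjusted p = 0.0278). With the receptor share as a covariate camera called the list higher (adjusted p = 1.08e-12), as it did in libraries of similar receptor share (adjusted p = 0.000924). Both higher calls ended with an estimated correlation (adjusted p = 0.0834 and 0.349 with an estimated correlation). FoxO target genes had 2 of 22 lower, Sod2 (-0.98, SE 0.24) and Il7r, and no list call (adjusted p = 0.0757). Camera called the list lower without deleted replicate 1 (adjusted p = 0.0314) or 4 (adjusted p = 0.0435). It also did so without control replicate 1 (adjusted p = 0.0429) or 2 (adjusted p = 0.00715), and with no low-count filter (adjusted p = 0.0472). The list was called higher with the receptor share as a covariate (adjusted p = 2.08e-07; adjusted p = 0.143 with an estimated correlation) and in libraries of similar receptor share (adjusted p = 0.027; adjusted p = 0.416 with an estimated correlation). In the fit on expressed genes, 2 of 14 FoxO target genes rose (Klf2 and Bcl2l11, named after their values were seen) and Sod2 and Il7r fell, with no list call (adjusted p = 0.41).

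None of 29 Hippo pathway components passed the test over all genes, also when adjusted over the list alone; Rassf5, which encodes a partner of the deleted kinases, had the smallest p, at -0.75 (SE 0.30, adjusted p = 0.113). Of 23 YAP/TAZ target genes only Nt5e fell, and the list was not called (adjusted p = 0.424). With expressed genes alone, and the upward move of 0.41 given above, 2 of 13 Hippo components rose, Taok1 (0.65, SE 0.20) and Stk38 (0.54, SE 0.19), which were at 0.29 and 0.11 over all genes. Of 7 YAP/TAZ target genes there, Nt5e fell and Dock5 rose (0.75, SE 0.23). Taok1, Stk38 and Dock5 are named after their values were seen, and neither list was called (adjusted p = 0.234 and 0.195).

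Oxidative phosphorylation genes fell in 54 of 67 cases (63 adjusted over the list alone), with Cox6c at -1.62 (SE 0.30), and 33 of 55 ribosomal protein genes fell (50 adjusted over the list alone), with Rpl30 at -2.05 (SE 0.28). Glycolysis genes fell in 12 of 18 cases (14 adjusted over the list alone), with Aldoa at -1.62 (SE 0.27). Cell cycle genes fell in 19 of 40 cases (21 adjusted over the list alone), with Rrm2 at -1.58 (SE 0.26). Camera with the preset correlation called each of these lists lower (adjusted p = 1.17e-30, 2.14e-29, 3.82e-10 and 4.29e-09). Oxidative phosphorylation and ribosomal protein genes had the smallest values of the 22 lists, below the effector list. The calls stayed among expressed genes (adjusted p = 1.65e-15, 1.1e-16, 0.000122 and 0.0158). They also stayed with the receptor share as a covariate (adjusted p = 0.0025, 0.0025, 0.00334 and 5.12e-06). With an estimated correlation their adjusted p was 0.129 for the first 3 lists and 0.1 for the cell cycle. The deleted libraries also had the larger receptor share.

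T helper programs fell in part. In the Th1 list 7 of 19 genes fell, with Nkg7 at -3.15 (SE 0.39) and the chemokine gene Ccl5 at -2.84 (SE 0.46), and Gzmk, named after its values were seen, rose by 1.38 (SE 0.37) from a low level (10 fell and 1 rose when adjusted over the list alone). In the Tfh list 6 of 13 fell (8 adjusted over the list alone), with Pdcd1 at -2.34 (SE 0.32) and Icos at -1.76 (SE 0.27). In the Th2 list 4 of 13 fell (5 adjusted over the list alone), with Ccr8 at -1.57 (SE 0.29), and in the Th17 list 2 of 15 fell (2 adjusted over the list alone), Ccr6 (-1.76, SE 0.26) and Maf (-1.59, SE 0.28). Camera called the first 3 of these lists (adjusted p = 4.36e-06, 1.26e-05 and 0.0155) and not Th17 (adjusted p = 0.0581). With an estimated correlation the adjusted p was 0.114 for Th1 and 0.129 for the others. The Th2 call ended among expressed genes (adjusted p = 0.193) and with the receptor share as a covariate (adjusted p = 0.433). With that covariate the Th1 and Tfh calls stayed in camera with the preset correlation (adjusted p = 0.000527 and 0.0227). Neither was called there with an estimated correlation.

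Among the remaining lists, IL-2-STAT5 targets fell in 10 of 22 cases (13 adjusted over the list alone; Tnfrsf18 -1.33), migration and adhesion genes in 13 of 33 (20; Itgb1 -2.41), interferon response genes in 10 of 28 (14; Ly6a -1.82) and immediate early genes in 6 of 23 (7; Junb -1.47). Genes of mTORC1 and cholesterol synthesis fell in 6 of 27 cases (6; Phgdh -1.60), apoptosis regulators in 4 of 25 (9; Bcl2l1 -1.43) and heat shock genes in 4 of 13 (6; Hspa1a -3.81 and Hspa1b -3.43, near-identical copies). Camera called each of these lists lower, and with an estimated correlation each had an adjusted p of 0.129. The deleted libraries also had the larger receptor share. Among expressed genes alone the calls ended for mTORC1 and cholesterol synthesis and for apoptosis regulators (both adjusted p = 0.979), immediate early genes (adjusted p = 0.193) and the interferon response (adjusted p = 0.0664). Of 25 migration and adhesion genes measured there, 3 fell, 1 rose (Rap1b, named after its values were seen) and 21 did not pass the test, with a median of -0.24 against -0.68 over all genes (adjusted p = 0.0173; adjusted p = 0.425 with an estimated correlation). With the receptor share as a covariate none of these 7 lists was called, with adjusted p of 0.985 for IL-2-STAT5 targets, 0.946 for heat shock, 0.825 for immediate early genes, 0.822 for apoptosis regulators, 0.327 for migration and adhesion, and 0.171 for the other two. In the fit on expressed genes, Pim1 of the IL-2-STAT5 list and Bcl2l11 of the apoptosis list, named after their values were seen, rose.

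The largest values among higher genes belonged to genes of low count. Olfr731 was at 24.2 ± 9.39 CPM in deleted and 3.89 ± 3.64 CPM in control libraries, a log2 fold change of 2.67 (SE 0.58, adjusted p = 0.00684). Olfr16 (2.27), the serotonin receptor gene Htr4 (2.15), Ccn3 (2.05), Ly6k (1.93), Cphx3 (1.64), Vmn2r83 (1.64) and Olfr559 (1.63) followed. None of these 8 genes passed the test with the receptor share as a covariate. The receptor genes among them are part of that share, and the SE of each of the 8 was larger there. Cphx3 moved up to 1.86 (SE 0.52, against 0.35 without it) and Olfr559 to 2.01 (SE 0.63, against 0.44). The others moved down, such as Olfr731 to 1.21 (SE 0.66). The loss of these calls therefore does not show that background accounts for the rises. Of the 400 higher genes, 53 were olfactory or vomeronasal receptors, 30 were T cell receptor alpha or delta segments and 35 had at least 50 mean CPM.

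The authors' deposited table held 632 genes higher and 1995 lower at a mean false discovery rate under 0.05. Of these, 379 higher and 1915 lower genes were also called here, and 97.3% of log2 fold changes had the same sign. Across genes, which are not independent replicates, the 2 sets of log2 fold changes had Pearson's r of 0.996. Both rest on the same counts.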

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

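The tests weighed here were chosen after the results were seen. Among 144 sets of 6 or 7 libraries examined for a single library far from the rest, 7 had one, and chance alone gives about 7.2. Deleted replicate 1 accounted for 4 of them. Its Olfr731 level was low (3.08 on the log2(CPM + 1) scale, the others 4.58 to 5.19; gap over range 0.712), its Bcl2l1 level high (5.28, the others 4.19 to 4.52; 0.701) and its Rpl3 level high (6.73, the others 5.26 to 5.80; 0.635). Its share of genes with a read was 95.3%, the others 97.4 to 98.1% (0.756). Over all genes, its log2 CPM had a correlation of 0.797 to 0.859 with the other deleted libraries, against 0.862 to 0.911 among those. Pairs of control libraries ranged from 0.822 to 0.925. Deleted replicate 4 had a high Cox6c level (7.13, the others 6.07 to 6.40; 0.684). Control replicate 5 had a high Bcl2a1d level (6.54, the others 5.01 to 5.52; 0.664), and control replicate 7 a low Tk1 level (4.20, the others 4.85 to 5.31; 0.586).

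Receptor genes that T cells do not use were higher, and abundant genes lower, in the deleted libraries. A switch-on by the deletion of genes without reads in control libraries was argued against. Counts per kb over olfactory receptor genes, not scaled to library totals, were 24.9 ± 3.36 (SD, n = 6) in deleted and 20.4 ± 2.84 (SD, n = 7) in control libraries. The control over deleted ratio was 0.821 with a spread of 0.159. As a share of the total count, receptor genes were at 0.712% in control and 1.29% in deleted libraries, so a partial rise was not tested. Olfactory, vomeronasal and bitter taste receptor genes had similar counts per kb, at most 2.24 times apart within a library, which is consistent with reads that do not depend on transcription, such as genomic DNA. Such reads may weigh more where less RNA was captured, and the libraries with fewer counts had the larger shares. Whether the deleted cells yielded less RNA for a biological reason was not tested.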

How the results depend on the processing

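The fits on expressed genes, at every cutoff, and those using the receptor share were chosen after seeing the data. Against 400 higher and 2050 lower genes, upper quartile scaling gave 761 and 1208, 1 surrogate variable 77 and 153, expressed-gene scaling 1213 and 684, the receptor share as a covariate 36 and 36, and libraries of similar share 38 and 101. DESeq2 gave 688 and 2549, and limma-voom with sample weights 1174 and 2938. A log2 fold change of at least 1 left 233 and 1144. Expressed genes alone gave 561 higher and 717 lower at 50 mean CPM, 684 and 1036 at 30, 479 and 570 at 64, 289 and 289 at 100, and 92 and 80 at 200, with fewer genes tested at each higher cutoff. Of the 561 higher genes, 35 were among the 400. Elsewhere the cause was not tested.

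Without 1 library the higher count ranged from 167 to 860 and the lower count from 1034 to 3245. It moved by over 1.5 times without deleted replicates 2 (219 and 1361), 3 (199 and 1148), 5 (222 and 1034) and 7 (167 and 1080), control replicates 4 (195 and 1141), 5 (220 and 1116), 2 (860 and 3245) and, for higher genes, deleted replicate 1 (602) and control replicate 6 (253). The replicate number as a block gave 121 and 736. That fit also left out control replicate 6, which has no deleted library of its number. Leaving out this library alone, without a block, gave 253 and 1428. Same-numbered libraries did not deviate together (r from -0.209 to 0.113). The counts thus showed no pairing by number, but shared litters or handling were not tested.

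Camera called 17 lists lower and 0 higher, and 17 to 19 lower and 0 higher without any 1 library. With an estimated correlation it called 0, also among expressed genes and with the receptor share as a covariate, and 3 lower in libraries of similar share (effector Treg, cell cycle and Th1). With the preset correlation camera called 9 lower with the receptor share as a covariate and at 64 mean CPM, 5 at 100 and 2 at 200. With the preset correlation it also called 2 higher (resting Treg and FoxO targets) with 1 surrogate variable, with the covariate, in libraries of similar share, and at 100 and 200. The effector list was lower at 30, 50, 64 and 100 mean CPM (adjusted p = 1.52e-13, 8.35e-10, 9.49e-06 and 0.0137) and had too few members at 200. Fry, which tests whether a list's genes move one way and does not compare them with other genes, was run over all genes and called 18 lower and 0 higher, Th17 (adjusted p = 0.00116) among them.

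Genes that did not pass the test changed sign without passing it. Stk3 (-0.01) was at 0.18 with upper quartile scaling, 0.0745 with the stricter filter, 0.0741 with 1 surrogate variable, 0.28 at 30 mean CPM, 0.37 with expressed-gene scaling, 0.0094 with limma-voom, and -0.11 to 0.0932 without 1 library. Stk4 (-0.31) was at 0.28 with 1 surrogate variable, 0.0567 among expressed genes, 0.0568 with their scaling, 0.10 at 64 and 0.20 at 100 mean CPM, 0.54 with the covariate, 0.0621 in libraries of similar share, and -0.75 to -0.14 without 1 library. Foxp3 was at 0.16 with 1 surrogate variable, 0.0812 with expressed-gene scaling, 0.32 with the covariate and 0.0075 in libraries of similar share. Rassf5 was at 0.21 with 1 surrogate variable, 0.16 at 200 mean CPM and 0.30 with the covariate. Of the other values of single named genes, 1472 kept their side of the threshold, 159 lost it and 2 gained it.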

Other observations

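The tests that weigh the effector Treg genes and the T cell receptor segments were chosen, or reworded, after the results were seen. Transcripts of other immune cells moved in both directions; the genes named here were chosen after their values were seen. Of the B cell list Ighm, the immunoglobulin mu constant region gene, fell by 2.81 (SE 0.33), from 596 ± 254 CPM (SD, n = 7) to 85.2 ± 27.4 CPM (SD, n = 6). Cd79b fell by 1.52 and Igkc, at 4.42 ± 3.37 CPM in deleted and 19.1 ± 9.94 CPM in control libraries, fell too, while Ms4a1 rose by 0.64. Of the dendritic cell list Cd74, the invariant chain gene, fell by 1.85, Cst3 fell by 1.33 and Bst2 fell by 1.11, while Xcr1 and Clec9a rose by 0.71 and 1.02. Among expressed genes alone, the 1 B cell gene measured fell. Of 2 dendritic cell genes there, 1 fell and 0 rose. Receptor genes had a median of 0.58 over all genes, so rises near that size were not told apart from background. Camera called none of the 12 lists of other cells and sex-linked genes. The smallest adjusted p was 0.327, for NK cells, whose 12 genes all missed the threshold in edgeR. The adjusted p was 0.428 for macrophages, neutrophils, erythroid cells and sex-linked genes, 0.431 for conventional CD4 T cells, 0.434 for stromal cells, 0.589 for CD8 T cells and 0.642 for B cells, plasma cells, dendritic cells and platelets. These values do not show equal amounts of other cells, since few of the genes were expressed (1 of 15 in the B cell list). The B cell list had a median of 0.29 although Ighm fell. Fry's test for changes in either direction gave this list an unadjusted p of 4.34e-07, the smallest of the 12.

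The lower effector Treg genes were weighed against 2 explanations. The larger share of background reads was not excluded. Among expressed genes alone the list was still lower (camera p = 1.19e-10), although an estimated correlation ended the call (adjusted p = 0.111). Ribosomal protein and oxidative phosphorylation genes were lower there too (camera adjusted p = 1.1e-16 and 1.65e-15). Passing this test therefore did not set the effector genes apart. With the receptor share as a covariate, camera with the preset correlation gave the effector list an adjusted p of 6.31e-16. The ribosomal protein and oxidative phosphorylation lists were both at 0.0025 there. An estimated correlation ended the effector call with this covariate too, and the covariate was correlated with genotype. Fewer Treg cells in the sort stays open: with expressed-gene scaling the median of the 21 Treg signature genes was -0.61 against an effector median of -0.88, a difference of 0.272 (SE 0.328), within the error. A first version of this test used Foxp3 (0.0812), Ikzf2 (-0.44) and Il2ra (-0.57) alone, whose mean of -0.31 lay 0.575 (SE 0.257) above the effector median. The signature list was set beside it because these genes were picked after their values were seen and the margin rested on Foxp3. The signature list and these genes disagreed, so the explanation was not settled. A smaller effector fraction among Treg cells, Cre zygosity and lower RNA capture in the deleted libraries were not separated from genotype.

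T cell receptor alpha V segments took 0.162 ± 0.107% of counts in deleted (SD, n = 6) and 0.0727 ± 0.0213% in control libraries (SD, n = 7; two-sided exact permutation p = 0.0332). Relative to the constant region gene Trac, V segment counts were 3.81 ± 2.68 times as many in deleted and 1.12 ± 0.315 times in control libraries (exact permutation p = 0.00117; 2.80 ± 1.13 without deleted replicate 1, exact permutation p = 0.00253), whereas the beta chain ratio was 0.481 ± 0.0349 and 0.467 ± 0.0284 (exact permutation p = 0.415). Unrearranged genomic DNA stays open: after subtracting the counts per kb of Ighv segments the difference did not pass the test (exact permutation p = 0.188); a first version of this test, V segments over 1.5 times the Ighv rate, was met by 4 of 6 deleted but also 5 of 7 control libraries and was replaced because ordinary alpha chain RNA meets it. Unspliced nuclear RNA stays open too: Trav and Malat1 percent had Pearson's r of 0.488 (permutation p = 0.0957) and Spearman's rho of -0.0549 (permutation p = 0.864), and r of -0.379 (SE 0.285) without deleted replicate 1 and control replicate 6, so the relation rests on those libraries. Thymocytes cannot be told apart from background, since the median of their 10 markers, 0.424 below that of the receptor genes (-0.424, SE 0.158), came from genes near background level (25.7 CPM). Rag2, named after its values were seen, rose by 0.84 (SE 0.26, adjusted p = 0.0378), and no other marker passed the test.

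Of 100 splits of the 13 libraries into 6 and 7, 2 gave at least as many calls as the real split, itself included. At the level of 0.05 this argues against a random split of the libraries as the source of the 2450 calls. The highest other split gave 2800 calls and the next 1787, with receptor shares differing by -0.478 and 0.556 percentage points between their sides, while 96 gave 0. The first of these splits matched genotype for 10 of 13 libraries and the second for 9 of 13, so that an effect of genotype carried over into them was not separated from another structure of the samples. Another split with a difference of -0.489 in receptor share gave 0 calls.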
